A study of Mus musculus with 14 samples.

How the data were processed

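Bulk polyA RNA was sequenced from about 1 cm3 of tumour tissue per sample, taken 2 months after transplantation, with paired reads of 150 bp, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, which gave 12 bulk libraries in 4 groups of 3. The series also holds 2 single-cell samples, which were not analysed here. Reads were aligned to mm10 with STAR 2.6.0 and DESeq2 was used, per the submitters' processing notes, which also name Seurat 3. The read counter, the annotation and the use of strand are not given in the sources used here, so genes with near-identical copies or an antisense partner, such as Gbp2b, Clca3a2, Reg3b, the H2 genes and Xist, have uncertain levels.

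The authors deposited 2 tables of whole-number counts per gene, one for the 9 subcutaneous libraries and one for the 3 orthotopic and 3 subcutaneous TMPC libraries. Beside them, per the file headers, stand normalized counts, a signal that the authors made by dividing counts by a size factor per library. The tables also hold the authors' log2 fold changes and the authors' DESeq2 adjusted p-values, which are quoted only where the authors' deposited table is named. Each table has 24421 entries. In the subcutaneous table the symbols stand out of step with the counts from entry 12291 on, which affects 12131 entries, because 2 entries with a repeated symbol are absent from the symbol column. Symbols were therefore taken by position from the second table, whose counts for the subcutaneous TMPC libraries were equal in all 24421 entries. As a check, counts were compared with the deposited normalized signal times the size factor, within 0.01 reads in all 9 libraries. They matched for 14200 of 24419 genes as deposited and for 24419 after realignment. A spreadsheet had turned 27 symbols into dates, of which 26 were restored through the Ensembl identifier. Of 23104 Ensembl identifiers 23078 were found in the reference names, and gene positions come from the mm10 reference annotation. No entry lacked a gene (0 entries).

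Total counts ranged from 16584781 to 21107310 per library, so that 3 counts correspond to between 0.142 and 0.181 CPM. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Pairs of libraries within a group differed by a chi-square of 28.4 to 429 per degree of freedom, so no pair was a duplicate. CPM values, counts scaled to a common library total, used TMM factors, except those of the plot of Xist and the Y-linked genes, which are per total count.

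Counts were tested with edgeR 4.0.16 in R 4.3.3 by glmQLFit and glmQLFTest with TMM factors and filterByExpr. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 9 subcutaneous libraries were fitted together, with 6 residual degrees of freedom, and the 6 libraries of the site comparison on their own, with 4. The standard error of a log2 fold change was its size divided by the square root of the F statistic. An exact permutation test of 3 against 3 libraries cannot give a two-sided p under 0.1, so none was used for single genes. The same steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For TMP against TM edgeR found 1% and 48% of them, for TMPC against TMP 0% and 50%, for TMPC against TM 3% and 53%, and for the sites 1% and 33%. Of edgeR's calls 2%, 9.09%, 1.75% and 0% fell on unchanged genes, against 36.1%, 33.5%, 38.2% and 34.8% for DESeq2 1.42.0. The real comparisons with TM and of the sites had many more calls than there were changed genes in these simulations. With few changed genes the adjustment is stricter and false calls make up a larger share. The percentages therefore do not carry over to those comparisons.

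Gene lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members, and again with a correlation estimated per list. The 43 lists covered gastric and other epithelial cell types, immune and stromal cells, neighbouring organs, signalling targets, metabolism, stress, cancer drivers and sex-linked genes. Of these 39, 39, 39 and 40 could be tested in the 4 comparisons. The erythroid list (8 of 10 members in the table) and the list of genes encoded by the mitochondrial genome (0 of 13) could be tested in none. The lists, tests, groups, alternatives and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the 8 largest rises and the 8 largest falls past the threshold with groups that do not overlap and a mean of at least 5 CPM, leaving out predicted genes and variable segments of immune receptors. It added the 3 members with the smallest adjusted p of each list past the threshold, cancer driver genes chosen by name (among them Trp53, Myc, Cdh1, Cdkn2a, Apc, Smad4 and Arid1a) and other drivers past the threshold. It gave 307 pairs of gene and comparison, of which 161 are named, and results for some of the genes it gives are not reported here. For genes at 0 counts in a group, the fold is a lower bound against 3 counts over the group, and for 1 to 3 counts it is a ratio with a 95% Poisson interval.

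Alternatives were DESeq2's Wald test, median-of-ratios size factors in edgeR, no filter on low counts, a filter at a mean count of 100, a fold threshold, only the 2 groups compared in the fit, the replicate number as a block, an estimated correlation for lists, and leaving out each library in turn. Calls shared by the comparisons with TM were set beside 20 simulations of unchanged groups against the same TM libraries. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.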

Results

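Messenger RNA was sequenced from mouse gastric tumours grown from transplants in 2 places, under the skin (subcutaneous) or in the organ of origin (orthotopic). The 12 libraries formed 4 groups of 3: subcutaneous TM, subcutaneous TMP, subcutaneous TMPC and orthotopic TMPC. The labels do not spell out TM, TMP or TMPC, which are used here as names only. Tissue was collected 2 months after transplantation. Total counts per library ranged from 16584781 to 21107310, and between 17122 and 18363 genes had at least 1 count. Nothing in the labels says that the replicates came from separate animals, so p-values measure the spread between these libraries, which may be technical. Gene positions are given on the mm10 build.

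Replicate 2 of the subcutaneous TM group stood apart from the other libraries. It had 0 counts over the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, where the other 11 libraries had 493 to 5420. Its mean correlation across genes with the libraries of its own group was 0.764, against 0.875 and 0.868 for replicates 1 and 3. Epcam, a surface protein of epithelial cells, stood at 55.2 CPM (counts scaled to a common library total) in it against 458 and 535 CPM in replicates 1 and 3. Jchain, a plasma cell gene, stood at 2250 CPM against 1.71 and 5.58 CPM. Replicate 3 of the orthotopic group differed from the other orthotopic libraries in genes of neighbouring organs, with the liver gene Alb at 3130 CPM against 2.62 and 0.416 CPM. The genes given for single libraries, such as Epcam, Alb, Atp4b and the Y-linked genes, were chosen after their values were seen. Counts per gene group without these 2 libraries, also chosen after the data were seen, stand beside many of the groups. Counts of the other groups can move with these libraries as well.

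Subcutaneous TMP tumours were first set against subcutaneous TM tumours, to ask how tumours of these 2 labels differ at the same site. Xist, a gene of female cells, set the TM libraries apart, at 200 to 1250 CPM per total count against at most 12.4 elsewhere. Host sex, or another difference that goes with the group, therefore cannot be told apart from the label in comparisons with TM. Of 39 gene lists 16 passed, 5 higher and 11 lower in TMP tumours, and 0 passed with an estimated correlation (lowest adjusted p = 0.133). Lists of cell division, ribosome production and glycolysis genes were among the higher ones, and those of the interferon response and of several kinds of immune cell among the lower ones. Top2a, a DNA topoisomerase needed in dividing cells (chromosome 11, 98992943 to 99024189), rose from 113 ± 18.3 to 456 ± 26.3 CPM (SD, n = 3 per group). Oasl2, an interferon-induced gene (chromosome 5, 114896936 to 114912234), fell from 323 ± 109 to 39.6 ± 3.19 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4239 of 15277 genes passed, of which 2188 rose and 2051 fell.

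Cell cycle genes rose as a group, with 34 of 35 tested members higher in TMP tumours and the same number adjusted over the list alone. The median log2 fold change was 1.71 (adjusted p = 7.86e-31, and adjusted p = 0.133 with an estimated correlation). Bub1b, a spindle checkpoint kinase, rose by 2.36 ± 0.20 (log2, SE) and Ccna2, the S phase cyclin, by 2.10 ± 0.18. Of the Myc target and ribosome biogenesis list, 25 of 26 members rose, and 25 adjusted over the list alone, with a median of 1.27 (adjusted p = 2.46e-16, and adjusted p = 0.713 with an estimated correlation). Within it, the transferrin receptor gene Tfrc rose by 2.90 ± 0.28 and the nucleolar gene Nolc1 by 1.71 ± 0.20. Hypoxia and glycolysis genes rose in 11 of 20 cases, or 15 adjusted over the list alone, with a median of 1.61 (adjusted p = 8.27e-08, and adjusted p = 0.713 with an estimated correlation). Ldha, Pgk1 and Gapdh, all enzymes of glycolysis, rose by 1.86 ± 0.32, 2.06 ± 0.37 and 1.67 ± 0.28. In these lists 34, 25 and 17 members rose without TM replicate 2. Oxidative phosphorylation genes rose in 6 of 25 cases, or 0 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.0133, and adjusted p = 0.888 with an estimated correlation). Cox5b, a subunit of cytochrome oxidase, rose by 1.00 ± 0.27, and the list had 11 members higher without TM replicate 2 and did not pass without TM replicate 1 (adjusted p = 0.0598). Skeletal muscle genes had a median of 2.66, the same with the 2 members at 0 counts in a group set to their bound. Of 18 members 3 rose, or 0 adjusted over the list alone (adjusted p = 0.0473, and adjusted p = 0.888 with an estimated correlation). That list did not pass without TM replicate 2 (adjusted p = 0.168, median 4.21), TMP replicate 2 (adjusted p = 0.566, median 0.54) or TM replicate 1 or 3 (adjusted p = 0.114 and 0.0732), and its member Acta1, skeletal actin, stood at 31.7 ± 49.9 CPM in TMP tumours and 0.284 ± 0.206 CPM in TM tumours. The log2 fold change of Acta1, 6.86 ± 1.92, was 3.44 ± 1.18 without TMP replicate 2 (adjusted p = 0.091) and 7.48 ± 2.47 without TM replicate 2 (adjusted p = 0.0511).

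Interferon response genes fell in 28 of 32 cases, or 31 adjusted over the list alone, with a median log2 fold change of -3.52 (adjusted p = 5.48e-11, and adjusted p = 0.713 with an estimated correlation). Irf9, a transcription factor of interferon signalling, fell by 1.95 ± 0.25 and the antiviral gene Mx1 had a log2 fold change of -3.31 ± 0.52. In TM replicate 2 the mean log2 CPM of this list was 8.38, against 5.57 and 5.60 in TM replicates 1 and 3. Without that library 23 members fell and the median was -1.67. MHC class I antigen presentation genes fell in 8 of 15 cases, or 13 adjusted over the list alone (adjusted p = 0.00166, and adjusted p = 0.863 with an estimated correlation), and in 3 of 15 without TM replicate 2. The peptide loading genes Tapbp and Tap1 had log2 fold changes of -2.14 ± 0.51 and -4.03 ± 1.00. MHC class II genes fell in 3 of 10 cases, or 9 adjusted over the list alone (adjusted p = 0.00189, and adjusted p = 0.846 with an estimated correlation), and in 2 of 10 without that library. Ctss, a protease of class II processing, fell by 2.17 ± 0.46. The log2 fold changes of Mx1, Tapbp, Tap1 and Ctss without TM replicate 2 were -2.62 ± 0.35, -1.19 ± 0.18, -2.04 ± 0.46 and -1.49 ± 0.28.

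Cytotoxic and NK cell genes fell in 12 of 14 cases, or 14 adjusted over the list alone, with a median of -5.77 (adjusted p = 8.80e-05, and adjusted p = 0.803 with an estimated correlation). In the macrophage and monocyte list 11 of 22 genes fell, or 13 adjusted over the list alone, with a median of -1.82 (adjusted p = 1.11e-05, and adjusted p = 0.713 with an estimated correlation). Cd14, a coreceptor for bacterial lipopolysaccharide, and the integrin gene Itgam had log2 fold changes of -2.12 ± 0.26 and -2.89 ± 0.41. Of 16 neutrophil genes 9 fell, or 13 adjusted over the list alone (adjusted p = 0.000679, and adjusted p = 0.803 with an estimated correlation). T cell genes fell in 6 of 9 cases, or 8 adjusted over the list alone (adjusted p = 0.0108, and adjusted p = 0.713 with an estimated correlation). Log2 fold changes were -5.36 ± 0.98 for the formyl peptide receptor gene Fpr1, -4.13 ± 0.93 for Csf3r, -4.24 ± 0.91 for the NK cell receptor gene Klrb1c and -5.28 ± 1.35 for the T cell kinase gene Lck. With TM replicate 2 left out, the members that fell numbered 7 for cytotoxic and NK cells, 10 for macrophages, 6 for neutrophils and 3 for T cells, and the cytotoxic and NK cell median was -3.38 (-5.11 without TMP replicate 1). Without TM replicate 2 Csf3r, Klrb1c and Lck had log2 fold changes of -2.42 ± 0.47, -3.34 ± 0.80 and -2.89 ± 0.84. Lck had -6.80 ± 1.62 without TMP replicate 3. Dendritic cell genes fell in 5 of 15 cases, or 9 adjusted over the list alone, and cytokine and chemokine genes in 7 of 25 with 1 higher, the same adjusted over the list alone (adjusted p = 0.00982 for each list, and adjusted p = 0.888 with an estimated correlation for each). Immune checkpoint genes fell in 4 of 11 cases, also 4 adjusted over the list alone (adjusted p = 0.0297, and adjusted p = 0.713 with an estimated correlation). These lists did not pass without TM replicate 2, with adjusted p values of 0.168, 0.491 and 0.12. Among their members Irf8, Tnf and the alarmin gene Il33 had log2 fold changes of -4.22 ± 1.17, -3.18 ± 0.71 and -3.56 ± 0.82, or -1.55 ± 0.43, -2.23 ± 0.53 and -2.41 ± 0.58 without TM replicate 2. PI3K and FOXO target genes fell in 5 of 18 cases and rose in 1, the same adjusted over the list alone (adjusted p = 0.0368, and adjusted p = 0.713 with an estimated correlation), and had adjusted p values of 0.12 without TM replicate 2 and 0.09 and 0.0614 without TMP replicates 2 and 3. Txnip, an inhibitor of glucose uptake, fell by 3.03 ± 0.33, and Pik3ip1, an inhibitor of PI3K, fell by 1.86 ± 0.28.

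Several genes with large changes were undetected in the TM group. Pax1, a paired-box transcription factor of the developing skeleton (chromosome 2, 147361925 to 147393295), had 0 counts in TM tumours and was at least 356-fold higher in TMP tumours, against a floor of 3 counts over the group. On the same scale Fndc3c1 was at least 596-fold and Esx1 at least 100-fold higher. Slitrk5, a neuronal membrane protein gene, had 1 count over the TM group, for a ratio of 834 with a 95% counting (Poisson) interval of 150 to 33000. Xist, the RNA that silences an X chromosome in female cells (X chromosome, 103460366 to 103483254), fell by 9.26 ± 2.02, from 659 ± 722 to 1.06 ± 0.765 CPM. Its log2 fold change without TM replicate 2 was -7.80 ± 1.58 (adjusted p = 0.0095), and without TMP replicate 3 it was -9.87 ± 2.67 (adjusted p = 0.0542). Reads from Xist and its antisense partner Tsix would be counted together if strand was ignored, which the sources used here do not give. The log2 fold change of Jchain was -12.05 ± 3.11, with 31423 of its TM counts in replicate 2, and that of Clca3a2, of a chloride channel regulator family whose similar members make its level uncertain, was -8.74 ± 1.51. These were -4.37 ± 1.04 and -6.00 ± 0.56 without TM replicate 2, and Jchain had -12.98 ± 4.21 without TMP replicate 3 (adjusted p = 0.0818). Cxcl9 and Gbp2b, both induced by interferon gamma, the second of a family with near-identical members that makes its level uncertain, had log2 fold changes of -7.78 ± 2.45 and -7.48 ± 2.13, and neither passed without TM replicate 2, at -1.84 ± 1.11 and -2.52 ± 0.95 (adjusted p = 0.235 and 0.0765). Without TMP replicate 1 Cxcl9 had -7.13 ± 2.83 (adjusted p = 0.135).

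Of the cancer driver genes, Ccne1, which encodes cyclin E1, rose by 2.03 ± 0.43 (2.79 ± 0.18 without TM replicate 2), while Rb1 fell by 1.49 ± 0.33 and Tgfbr2, a TGF-beta receptor gene, fell by 1.54 ± 0.24. Of the 30 members of this list 2 rose and 2 fell, the same adjusted over the list alone, while 5 rose and 4 fell without TM replicate 2. Log2 fold changes that did not pass were 1.24 ± 0.62 for Myc (adjusted p = 0.168, or 0.63 ± 0.64 without TMP replicate 1 and 0.79 ± 0.41 without TM replicate 2), 0.53 ± 0.24 for Trp53 (adjusted p = 0.124) and 1.60 ± 0.78 for Cdkn2a. Cdh1, Apc, Smad4 and Arid1a had values of -0.14 ± 0.87, 0.23 ± 0.19, -0.11 ± 0.21 and 0.11 ± 0.18. Among the 23 lists that did not pass, the squamous, columnar, endothelium and smooth muscle lists had 0, 1, 0 and 0 members past the threshold, the fibroblast list 3 of 26 lower, and the B cell and plasma cell list 4 of 8 lower. Adjusted over the list alone, these numbered 0, 0, 0, 0, 0 and 6. With TM replicate 2 left out they numbered 3 lower, 1 lower, 2 higher, 1 higher, 6 lower and 3 lower. With all libraries, members that rose and fell numbered 1 and 1 of 17 for mesenchymal transition, 0 and 1 of 17 for stem cell and Wnt target genes, and 3 and 1 of 25 for p53 targets. They numbered 0 and 1 of 9 for mast cells and eosinophils, 1 and 1 of 12 for neural and Schwann cells, 1 and 0 of 20 for cholesterol synthesis, 2 and 3 of 20 for the unfolded protein response and 0 and 1 of 5 for sex-linked genes. These counts were the same adjusted over the list alone except for mesenchymal transition (0 and 1), mast cells (0 and 0) and cholesterol synthesis (0 and 0). Without TM replicate 2 the fibroblast, gastric pit and intestinal lists also passed, each lower in TMP tumours (adjusted p = 0.00946, 0.00622 and 0.0258, and adjusted p = 0.674, 0.544 and 0.481 with an estimated correlation). So did the gastric neck and chief cell list, also lower, which had too few tested members with all libraries (adjusted p = 0.000822, and adjusted p = 0.25 with an estimated correlation). Median and mean had opposite signs for the columnar list, at 0.24 and -0.05 with the test upward, and for the sex-linked list, at 1.00 and -0.82 with the test upward. The groups did not overlap for 49.7% of genes, where chance gives 10%. Leaving out TMP replicate 1, 2 or 3 reduced the genes past the threshold to 1550, 2132 and 1870 and ended 19, 15 and 16 of the 39 calls on named genes, and leaving out TM replicate 1, 2 or 3 ended 4, 4 and 4. The highest adjusted p among those calls was 0.135, 0.119 and 0.128 without the TMP replicates (Cxcl9) and 0.0821, 0.235 and 0.0853 without the TM replicates (Acta1, Cxcl9 and Acta1). The 19 calls that some planned setting ended were those of Acta1, Cox5b, Csf3r, Ctss, Cxcl9, Esx1, Fndc3c1, Gbp2b, Il33, Irf8, Jchain, Klrb1c, Lck, Pax1, Rb1, Tap1, Tapbp, Tnf and Xist, and the other 20 passed in every planned setting.

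**Figure D1:**
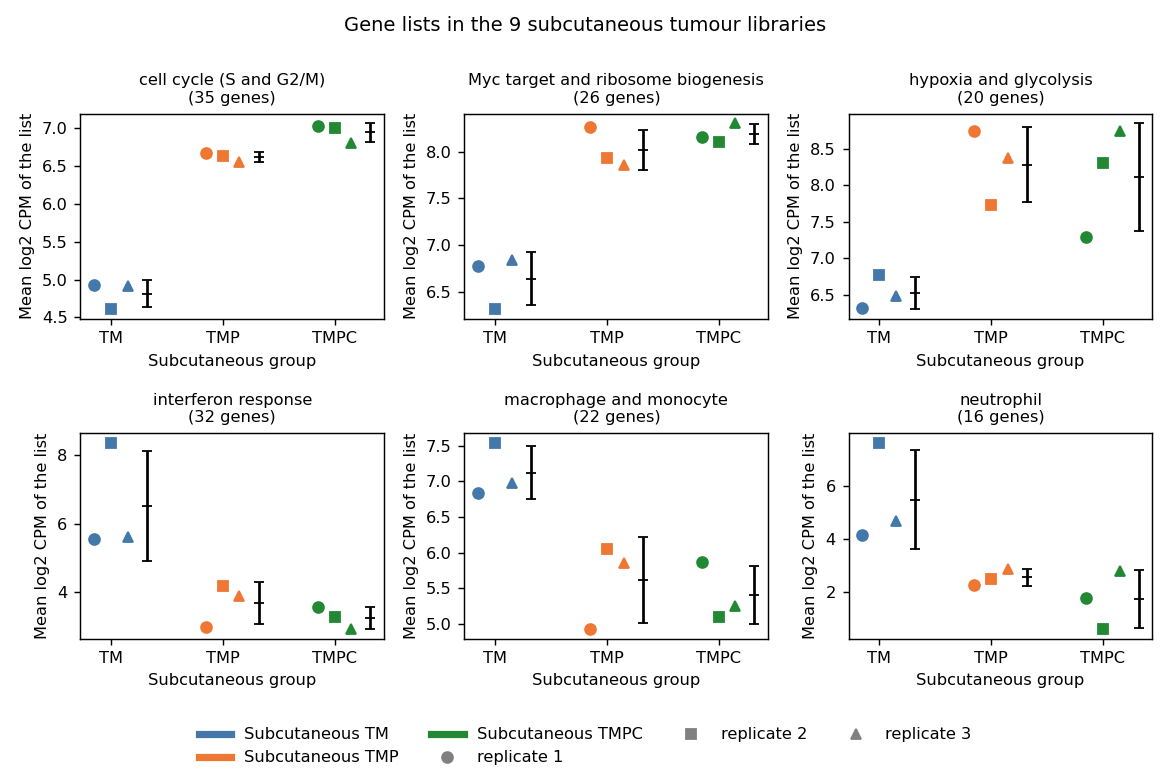
Mean log2 CPM (vertical axis) of 6 gene lists in the 9 subcutaneous libraries by group (horizontal axis), with a point per library and a black bar for the group mean ± SD. Cell cycle means lie at 4.61 to 4.93 in TM and at 6.55 to 7.03 in TMP and TMPC, and in the interferon panel TM replicate 2 lies at 8.38, above 5.57 and 5.60 in the other TM libraries.

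Subcutaneous TMPC and TMP tumours were then compared, and no gene passed in edgeR. Of 15277 genes, 465 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance gives, and 0 passed the adjustment, while DESeq2 called 16. With TM replicate 2, which is in neither group, left out of the edgeR fit, 1144 of 15668 genes had such a p. With only these 2 groups fitted, 817 of 14504 did, and 0 passed in either fit. The test was thus strict here, and 0 calls do not show that the groups are alike. Mcm2, a DNA replication helicase gene, stood at 148 ± 10.8 CPM in TMP and 210 ± 38.2 CPM in TMPC tumours (log2 fold change 0.51 ± 0.16, n = 3 per group), and Rrm2, a ribonucleotide reductase gene, had a log2 fold change of 0.94 ± 0.32. The antiviral gene Mx1 stood at 8.93 ± 2.70 and 2.78 ± 0.996 CPM (log2 fold change -1.68 ± 0.50). Each had an adjusted p of 0.9999. In data simulated for this comparison the same test found 0% of 2-fold and 50% of 4-fold changes. The groups did not overlap for 12.4% of genes, where chance gives 10%.

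Tested as lists, 16 of 39 passed, with 0 members past the threshold in any of them over all genes or adjusted over the list alone, and 0 lists passed with an estimated correlation. Cell cycle genes lay higher in TMPC tumours, with a median log2 fold change of 0.33 (adjusted p = 5.16e-13, and adjusted p = 0.319 with an estimated correlation), and Top2a had a value of 0.48 ± 0.16. Medians were 0.17 for the Myc target list (adjusted p = 0.00194), 0.16 for oxidative phosphorylation (adjusted p = 0.00415) and 0.85 for skeletal muscle (adjusted p = 5.25e-07), each with adjusted p = 0.871 with an estimated correlation. Odc1, the first enzyme of polyamine synthesis, had a log2 fold change of 0.45 ± 0.21 and the troponin gene Tnnt1 of 1.80 ± 0.71. Lower in TMPC tumours lay the cytokine list with a median of -0.82 (adjusted p = 0.000393), interferon response with -0.45 (adjusted p = 0.00121), columnar epithelium with -0.51 and neutrophil with -0.65 (adjusted p = 0.00342 for both). The squamous, fibroblast and adipocyte lists had medians of -0.54, -0.47 and -2.05 (adjusted p = 0.00415 for each) and the gastric pit list -0.74 (adjusted p = 0.0349). All 8 of these had adjusted p = 0.871 with an estimated correlation. TGF-beta target, immediate early, intestinal and endothelium genes had medians of -0.30, -0.34, -0.67 and -0.36 (adjusted p = 0.00194, 0.00352, 0.0188 and 0.0255, and adjusted p = 0.307, 0.319, 0.319 and 0.879 with an estimated correlation). Among members, the tight junction gene Cldn3 had a log2 fold change of -1.30 ± 0.80, Ltbp2 -0.85 ± 0.26, Cyr61 -1.12 ± 0.37, Jun -0.61 ± 0.23 and the matrix gene Dcn -1.40 ± 0.68. Medians moved to 3.87 and 0.22 for skeletal muscle without TMP replicate 2 and without TMPC replicate 2, to -1.58 for gastric pit and -3.30 for adipocyte without TMPC replicate 1, and to -1.54 for squamous and -1.45 for neutrophil genes without TMPC replicate 3. The median and mean differed in sign for 5 lists, none of which passed: cancer driver, gastric parietal, neural, cholesterol synthesis and sex-linked.

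The 7 driver genes named in every comparison had log2 fold changes within about 1 SE of 0 in TMPC against TMP. These were 0.20 ± 0.24 for Trp53, 0.07 ± 0.62 for Myc (0.71 ± 0.66 without TMP replicate 1), -0.88 ± 0.88 for Cdh1 and 0.06 ± 0.76 for Cdkn2a. Those of Apc, Smad4 and Arid1a were 0.15 ± 0.19, 0.16 ± 0.21 and 0.05 ± 0.18. In TMPC replicate 1 the epithelial genes Epcam and Cdh1 stood at 113 and 105 CPM, against 608 and 292 CPM in replicate 2 and 649 and 365 CPM in replicate 3. Without TMPC replicate 3, 9 lists passed instead of 16. The cell cycle, cytokine and TGF-beta target lists passed without each of the 6 libraries in turn. Those that did not pass were the columnar, immediate early and intestinal lists (adjusted p = 0.0529, 0.0556 and 0.124) without TMP replicate 1. Without TMP replicate 2 these were the adipocyte, endothelium, fibroblast, interferon and oxidative phosphorylation lists (adjusted p = 0.0727, 0.373, 0.343, 0.0844 and 0.286). Without TMP replicate 3 they were the endothelium, gastric pit, intestinal, Myc target and neutrophil lists (adjusted p = 0.128, 0.304, 0.0533, 0.0966 and 0.0802). The columnar, intestinal and squamous lists did not pass without TMPC replicate 1 (adjusted p = 0.605, 0.337 and 0.449). The same held for the gastric pit, intestinal, neutrophil and skeletal muscle lists (adjusted p = 0.467, 0.342, 0.57 and 0.0538) without TMPC replicate 2. It held for the adipocyte, endothelium, fibroblast, gastric pit, immediate early, interferon, Myc target and oxidative phosphorylation lists (adjusted p = 0.242, 0.22, 0.545, 0.137, 0.106, 0.0717, 0.112 and 0.663) without TMPC replicate 3.

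Subcutaneous TMPC tumours against TM tumours gave 5469 of 15277 genes past the threshold, with 2748 higher and 2721 lower in TMPC tumours. Top2a rose by 2.50 ± 0.17 on the log2 scale (SE, n = 3 per group), and Oasl2 fell by 3.62 ± 0.30. Pax1 and Esx1, at 0 counts in TM tumours, were at least 1410-fold and 924-fold higher, against 3 counts over the TM group. The bound was 470-fold for Pax1 without TMPC replicate 2 and 114-fold for Esx1 without TMPC replicate 1, with TMPC levels of 1.57, 179 and 49.5 CPM for Pax1 and 138, 5.5 and 6.83 CPM for Esx1. Fndc3c1 was at least 273-fold higher (79.5-fold without TMPC replicate 1), and Slitrk5 had a ratio of 996 with a 95% counting interval of 179 to 39300. Cyp2b10, a cytochrome P450 gene, had 0 counts in TMPC tumours and was at least 483-fold lower there (229-fold without TM replicate 3). Jchain, with 3 counts over the TMPC group, had a ratio of TM to TMPC of 14300 with an interval of 4890 to 69300, and 31423 of its TM counts lay in replicate 2, without which the ratio was 69.3 (23.7 to 336). Clca3a2 and Gbp2b had log2 fold changes of -9.24 ± 1.56 and -9.23 ± 2.32, or -6.48 ± 0.58 and -4.26 ± 1.02 without TM replicate 2. Gbp2b had -10.93 ± 2.99 without TMPC replicate 1 and -8.60 ± 2.78 without TMPC replicate 2 (adjusted p = 0.0646).

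In the cell cycle list 34 of 35 genes rose, also 34 adjusted over the list alone, with a median of 2.22 (adjusted p = 2.10e-31, and adjusted p = 0.138 with an estimated correlation). Mcm2 rose by 2.22 ± 0.16 and Birc5, a mitotic survival gene, by 2.18 ± 0.17. Of the Myc target list 25 of 26 genes rose, also 25 adjusted over the list alone, with a median of 1.49 (adjusted p = 3.16e-16, and adjusted p = 0.641 with an estimated correlation), and Tfrc and Nolc1 rose by 3.22 ± 0.29 and 2.01 ± 0.20. Hypoxia and glycolysis genes rose in 12 of 20 cases, or 15 adjusted over the list alone (adjusted p = 5.05e-06, and adjusted p = 0.706 with an estimated correlation), with Gapdh higher by 1.88 ± 0.28. Skeletal muscle genes rose in 6 of 18 cases, or 10 adjusted over the list alone (adjusted p = 0.000729, and adjusted p = 0.706 with an estimated correlation), with Acta1 higher by 7.65 ± 1.97 and a median of 3.72, the same with 2 members at their bound. Oxidative phosphorylation genes rose in 8 of 25 cases, also 8 adjusted over the list alone (adjusted p = 0.00107, and adjusted p = 0.706 with an estimated correlation), with Cox7a2, a cytochrome oxidase subunit, higher by 1.16 ± 0.25. When TM replicate 2 was left out, the members that rose numbered 35, 25, 16, 5 and 14 in these 5 lists, the skeletal muscle median was 4.82 (2.06 without TMPC replicate 2) and Acta1 had a log2 fold change of 8.30 ± 2.52.

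Interferon response genes fell in 30 of 32 cases, or 31 adjusted over the list alone, with a median of -4.01 (adjusted p = 1.29e-10, and adjusted p = 0.706 with an estimated correlation). Irf9 fell by 2.31 ± 0.25 and Mx1 had a log2 fold change of -4.99 ± 0.56. Without TM replicate 2, 27 members fell and the median was -1.89. MHC class I genes fell in 11 of 15 cases, or 13 adjusted over the list alone (adjusted p = 0.00258). MHC class II genes fell in 7 of 10, or 10 adjusted over the list alone (adjusted p = 0.00432). Both lists came with adjusted p = 0.706 with an estimated correlation. Cytotoxic and NK cell genes fell in 12 of 14 cases, or 13 adjusted over the list alone (adjusted p = 0.000557), and macrophage genes in 13 of 22, or 14 adjusted over the list alone (adjusted p = 1.52e-05). Neutrophil genes fell in 12 of 16, or 14 adjusted over the list alone (adjusted p = 0.000251), and T cell genes in 6 of 9, or 7 adjusted over the list alone (adjusted p = 0.0386). These 4 lists had adjusted p = 0.706 with an estimated correlation. Cytokine genes fell in 12 of 25 cases with 1 higher, or 16 with 1 higher adjusted over the list alone (adjusted p = 0.00072). Immune checkpoint genes fell in 5 of 11, or 6 adjusted over the list alone (adjusted p = 0.018). Both lists came with adjusted p = 0.706 with an estimated correlation. Dendritic cell genes fell in 8 of 15 cases, or 10 with 1 higher adjusted over the list alone (adjusted p = 0.0182, and adjusted p = 0.818 with an estimated correlation). Log2 fold changes were -2.43 ± 0.52 for Tapbp, -2.31 ± 0.46 for Ctss, -2.53 ± 0.27 for Cd14, -3.38 ± 0.41 for Itgam and -5.66 ± 1.00 for Fpr1. Without TM replicate 2 the members that fell numbered 8 for MHC class I, 4 for class II, 11 for NK cell, 12 for macrophage, 10 for neutrophil and 6 for checkpoint genes, and Mx1, Tapbp and Ctss had log2 fold changes of -4.29 ± 0.38, -1.47 ± 0.18 and -1.61 ± 0.28. Fpr1 had -6.70 ± 1.08 without TMPC replicate 1 and -5.03 ± 0.81 without TMPC replicate 2. The T cell, dendritic cell and cytokine lists did not pass without TM replicate 2 (adjusted p = 0.1, 0.188 and 0.0542).

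Gastric pit genes fell in 3 of 8 cases, or 5 adjusted over the list alone (adjusted p = 0.047, and adjusted p = 0.706 with an estimated correlation), with log2 fold changes of -4.39 ± 0.94 for the protease gene Ctse and -4.37 ± 1.29 for the mucin gene Muc5ac. Ctse had -6.20 ± 0.60 without TMPC replicate 1, and Muc5ac -3.53 ± 1.34 without TM replicate 1 and -3.77 ± 1.30 without TMPC replicate 2 (adjusted p = 0.0839 and 0.0766). PI3K and FOXO target genes fell in 6 of 18 cases and rose in 1, the same adjusted over the list alone (adjusted p = 0.042, and adjusted p = 0.706 with an estimated correlation). Endothelium genes fell in 2 of 18 cases, or 0 adjusted over the list alone (adjusted p = 0.0414, and adjusted p = 0.818 with an estimated correlation), with Vwf lower by a log2 fold change of -1.77 ± 0.52. Without TM replicate 2 these lists had adjusted p values of 0.00249, 0.1 and 0.965 (for the gastric pit list adjusted p = 0.486 with an estimated correlation). The gastric pit list did not pass without TM replicate 1 or 3 (adjusted p = 0.101 and 0.102), nor the PI3K and endothelium lists without TMPC replicate 3 (adjusted p = 0.0639 for each). The fibroblast, columnar and intestinal lists passed without TM replicate 2, each lower in TMPC tumours (adjusted p = 0.000398, 0.0123 and 0.0153, and adjusted p = 0.562, 0.638 and 0.486 with an estimated correlation). The gastric neck and chief cell list, with too few tested members with all libraries, was lower as well (adjusted p = 0.00249, and adjusted p = 0.359 with an estimated correlation). Median and mean had opposite signs for the cancer driver, squamous and sex-linked lists, and for the unfolded protein response list both were negative (-0.07 and -0.01) with the test upward. Among driver genes Ccne1 rose by 2.31 ± 0.44 (3.09 ± 0.19 without TM replicate 2) and Trp53 by 0.73 ± 0.24, while Rb1 fell by 1.56 ± 0.33 and Tgfbr2 fell by 1.97 ± 0.24. Of 30 driver list members 3 rose and 2 fell, or 1 and 2 adjusted over the list alone. Without TM replicate 2, 7 rose and 6 fell. Myc (1.31 ± 0.63, or 0.87 ± 0.41 without TM replicate 2), Cdkn2a (1.67 ± 0.78), Cdh1 (-1.02 ± 0.88), Apc (0.38 ± 0.19), Smad4 (0.05 ± 0.21) and Arid1a (0.16 ± 0.18) did not pass. Cdkn2a, Cdh1 and Apc each passed in 1 of 12 alternatives (adjusted p = 0.0495, 0.022 and 0.0376). The groups did not overlap for 47.1% of genes, where chance gives 10%. Without TMPC replicate 2, 3414 genes passed. Of 31 calls on named genes 25 passed in every planned setting, the other 6 being Acta1, Gbp2b, Jchain, Muc5ac, Trp53 and Vwf. Leaving out TM replicate 1, 2 or 3 or TMPC replicate 1, 2 or 3 ended 4, 1, 3, 2, 5 and 5 of those calls, with the highest adjusted p at 0.0839 (Muc5ac), 0.0588 (Vwf), 0.1 (Trp53), 0.0707 (Muc5ac), 0.0817 (Trp53) and 0.0879 (Trp53).

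The comparisons of TMP and of TMPC with TM share the TM libraries. Of their calls 2042 genes rose in both and 1884 fell in both, 3926 in all or 92.6% of the TMP calls, and 0 genes were called in opposite directions. Independent lists of these sizes would share 393.6 and 365.3 genes. In 20 simulations all 9 libraries, TM included, were drawn without a group difference, and 0 calls were shared. Such data hold no differences to call, so that 0 does not show how many shared calls come from using the same TM libraries. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.944, against 0.5 in the simulations, with a covariance of 2.53 against 0.205. The 3 control libraries are too few to be split, so part of the excess may come from their being shared. In the authors' deposited table, 7288 of 16739 genes had an adjusted p under 0.05 for TM against the others (3701 higher and 3587 lower), 12 of 15040 for TMP against the others and 198 of 15332 for TMPC against the others.

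**Figure D2:**
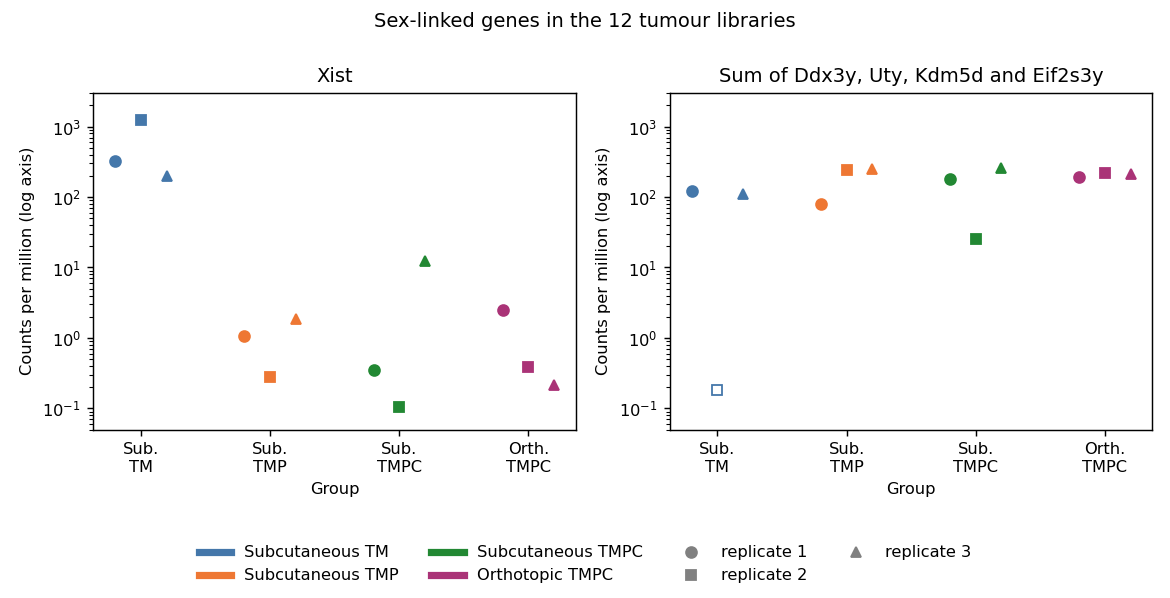
CPM, here per total count (vertical log axis), of Xist and of the sum of 4 Y-linked genes in each of the 12 libraries, by group (horizontal axis), where an open point marks 0 counts, drawn at the level of 3 counts. Xist lies at 324, 1250 and 200 in the TM libraries and at most at 12.4 in the others, and the Y-linked sum is 0 in TM replicate 2 and 25.7 in TMPC replicate 2.

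Orthotopic TMPC tumours were compared with subcutaneous TMPC tumours to ask what differs with the site of growth. Of 40 gene lists 25 passed, 20 higher and 5 lower in orthotopic tumours, and 0 passed with an estimated correlation (lowest adjusted p = 0.195). Lists of gastric pit, neck and chief cells and of the interferon response were among the higher ones, and those of cell division and ribosome production among the lower ones. Gkn2, a secreted protein of gastric pit cells (chromosome 6, 87373357 to 87379497), had 0 counts in subcutaneous tumours and was at least 35300-fold higher in orthotopic tumours, against 3 counts over the group. Kif11, a mitotic motor (chromosome 19, 37376403 to 37421859), fell from 256 ± 30.8 to 65.4 ± 12 CPM (SD, n = 3 per group). Myc (chromosome 15, 61985391 to 61990374) fell from 840 ± 54.7 to 111 ± 50.4 CPM. Of 15123 genes, 4204 passed in edgeR, with 2118 higher and 2086 lower in orthotopic tumours.

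Gastric pit cell genes rose in 12 of 12 cases, also 12 adjusted over the list alone, with a median log2 fold change of 7.22 (adjusted p = 5.87e-19, and adjusted p = 0.195 with an estimated correlation). Gkn1 had 3 counts over the subcutaneous group, for a ratio of 30600 with a 95% counting interval of 10500 to 149000. Gastric neck and chief cell genes rose in 7 of 9 cases, or 8 adjusted over the list alone, with a median of 7.16 (adjusted p = 1.16e-10, and adjusted p = 0.265 with an estimated correlation). The trefoil factor gene Tff2 had 1 count in subcutaneous tumours and a ratio of 22900 (4110 to 905000), the pepsinogen gene Pgc was at least 1610-fold higher, and the mucin gene Muc6 rose by 9.42 ± 0.74 (10.05 ± 0.91 and 8.81 ± 0.63 without subcutaneous replicates 1 and 3). Enteroendocrine genes rose in 5 of 10 cases, or 5 with 1 lower adjusted over the list alone (adjusted p = 0.00742, and adjusted p = 0.307 with an estimated correlation). The hormone gene Sst was at least 516-fold higher (341-fold without orthotopic replicate 1), and Hdc and Ghrl rose by 3.84 ± 0.68 (4.93 ± 0.32 without subcutaneous replicate 1) and 7.77 ± 1.45 (7.18 ± 1.48 without orthotopic replicate 1). Intestinal genes rose in 6 of 7 cases, also 6 adjusted over the list alone (adjusted p = 8.38e-05, and adjusted p = 0.195 with an estimated correlation), with the brush border gene Vil1 higher by 4.18 ± 0.48. Columnar epithelial genes rose in 5 of 20 cases, or 1 adjusted over the list alone (adjusted p = 0.00141, and adjusted p = 0.59 with an estimated correlation), with the keratin genes Krt8 and Krt19 higher by 1.70 ± 0.47 and 2.06 ± 0.54, the latter by 2.70 ± 0.46 without subcutaneous replicate 3. The claudin gene Cldn18 was at least 5340-fold higher. Parietal cell genes did not pass (3 of 9 higher, or 5 with 1 lower adjusted over the list alone, adjusted p = 0.0738). They stood apart by library, as the proton pump gene Atp4b was at 50.6 and 51.4 CPM in orthotopic replicates 1 and 2 and at 2.55 CPM in replicate 3. The milk-clotting protease gene Cym likewise stood at 2070, 5330 and 1.63 CPM, and its ratio to 1 subcutaneous count was 138000 (24900 to 5470000), or 58200 (10400 to 2300000) without orthotopic replicate 2 and 208000 (37300 to 8200000) without orthotopic replicate 3. Without orthotopic replicate 3 the parietal list passed with 7 of 11 genes higher (adjusted p = 2.33e-05, and adjusted p = 0.259 with an estimated correlation). The medians of the pit, neck and chief, enteroendocrine and columnar lists were the same with the genes at 0 counts set to their bound. Each list had 1 such gene, whose bound still lay above the median, so these medians could not move. Members higher without orthotopic replicate 3 numbered 12 of 12 for pit, 9 of 10 for neck and chief, 6 of 11 for enteroendocrine, 7 of 11 for intestinal and 6 of 20 for columnar genes. The neck and chief cell median was 8.22 without orthotopic replicate 3 and 8.05 without subcutaneous replicate 2. The pit and the neck and chief cell medians were 8.81 and 10.24 without subcutaneous replicate 1. All 4 are over fitted values that depend on the prior count for genes at 0 counts. Reg3b and the connexin gene Gjb1 were at least 3350-fold and 1970-fold higher, the first uncertain because it has close paralogs.

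Cell cycle genes fell in 32 of 35 cases, or 33 adjusted over the list alone, with a median of -1.38 (adjusted p = 6.73e-21, and adjusted p = 0.307 with an estimated correlation), among them Cdc20, an activator of mitotic exit (log2 fold change -1.58 ± 0.15). Myc target and ribosome biogenesis genes fell in 23 of 26 cases, or 25 adjusted over the list alone, with a median of -1.43 (adjusted p = 8.52e-17, and adjusted p = 0.307 with an estimated correlation). Cdk4 and Nolc1 had log2 fold changes of -1.25 ± 0.14 and -1.96 ± 0.26. Oxidative phosphorylation genes fell in 5 of 25 cases, or 0 adjusted over the list alone (adjusted p = 0.00323, and adjusted p = 0.59 with an estimated correlation). Hypoxia and glycolysis genes fell in 3 of 20, also 3 adjusted over the list alone (adjusted p = 0.0361, and adjusted p = 0.661 with an estimated correlation). Ndufv1 had a log2 fold change of -0.72 ± 0.15 and the pyruvate kinase gene Pkm of -1.21 ± 0.32. Skeletal muscle genes fell in 10 of 18 cases and rose in 1, or 11 and 1 adjusted over the list alone, with a median of -3.87 that was the same with 1 member at its bound (adjusted p = 6.81e-06, and adjusted p = 0.472 with an estimated correlation). Acta1 and Atp2a1, the muscle calcium pump, had values of -4.46 ± 0.95 and -5.20 ± 1.07, or -5.33 ± 1.09 and -6.14 ± 1.27 without orthotopic replicate 1. Without orthotopic replicate 3 the members that fell numbered 33, 25, 2, 3 and 11 in these lists, and the glycolysis list did not pass (adjusted p = 0.0868). That list did not pass either without orthotopic replicate 2 or subcutaneous replicate 2 or 3 (adjusted p = 0.108, 0.0672 and 0.266). Pax1, with 1 count in orthotopic tumours, had a ratio of subcutaneous to orthotopic of 4800 (861 to 189000), or 1600 (287 to 63200) without subcutaneous replicate 2. Esx1 and Slitrk5 had log2 fold changes of -7.33 ± 1.63 and -5.80 ± 0.74, and Slitrk5 -6.65 ± 0.76 without orthotopic replicate 2. Esx1 stood at 139, 5.61 and 6.98 CPM in the subcutaneous libraries, and had values of -4.34 ± 0.49 without subcutaneous replicate 1 and -7.93 ± 1.39 without subcutaneous replicate 2.

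Interferon response genes rose in 26 of 32 cases, or 30 adjusted over the list alone, with a median of 2.44 (adjusted p = 6.24e-18, and adjusted p = 0.265 with an estimated correlation), with the transcription factors Irf7 and Irf9 higher by 3.48 ± 0.40 and 1.54 ± 0.18. MHC class I genes rose in 10 of 15 cases, or 11 adjusted over the list alone (adjusted p = 2.20e-07, and adjusted p = 0.195 with an estimated correlation), with the peptide transporter gene Tap1 and the immunoproteasome gene Psmb9 higher by 1.98 ± 0.23 and 2.08 ± 0.22. MHC class II genes rose in 6 of 10 cases, or 8 adjusted over the list alone (adjusted p = 0.00048, and adjusted p = 0.4 with an estimated correlation), with Ctss and H2-DMa higher by 1.01 ± 0.16 and 1.39 ± 0.32. Without orthotopic replicate 3 the members that rose numbered 28, 9 and 6 in these lists. Macrophage genes rose in 4 of 22 cases (adjusted p = 0.00867, and adjusted p = 0.598 with an estimated correlation). Neutrophil genes rose in 4 of 16 (adjusted p = 0.0124, and adjusted p = 0.59 with an estimated correlation), both also 4 adjusted over the list alone. Cytokine genes rose in 6 of 24 cases, also 6 adjusted over the list alone (adjusted p = 0.00233, and adjusted p = 0.59 with an estimated correlation), and checkpoint genes in 3 of 8, or 4 adjusted over the list alone (adjusted p = 0.028, and adjusted p = 0.307 with an estimated correlation). B cell and plasma cell genes rose in 4 of 8, or 5 adjusted over the list alone (adjusted p = 0.0124, and adjusted p = 0.338 with an estimated correlation). Cd14, Csf1r, Il1b, Cd274 and Xbp1 rose by 2.12 ± 0.40, 1.46 ± 0.36, 3.63 ± 0.88, 1.71 ± 0.34 and 1.08 ± 0.19, and Il33 by 3.46 ± 0.40. Without orthotopic replicate 3 the macrophage, neutrophil, cytokine, checkpoint and B cell lists did not pass (adjusted p = 0.285, 0.342, 0.101, 0.111 and 0.173), and Il1b had a log2 fold change of 2.26 ± 0.50.

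Smooth muscle and pericyte genes rose in 11 of 16 cases, or 13 adjusted over the list alone, with a median of 2.33 (adjusted p = 2.96e-07, and adjusted p = 0.338 with an estimated correlation), with the pericyte channel gene Abcc9 and the myosin kinase gene Mylk higher by 2.43 ± 0.21 and 2.77 ± 0.33. Fibroblast genes rose in 2 of 26 cases, also 2 adjusted over the list alone (adjusted p = 0.0276, and adjusted p = 0.661 with an estimated correlation), namely the matrix proteoglycan genes Dcn and Lum, by 3.09 ± 0.40 and 2.41 ± 0.46, the latter 3.02 ± 0.23 without subcutaneous replicate 2. Endothelium genes rose in 3 of 18 cases, or 0 adjusted over the list alone (adjusted p = 0.00641, and adjusted p = 0.598 with an estimated correlation), with Kdr higher by 1.5 ± 0.41. Pancreas and liver genes rose in 3 of 9 cases, or 9 adjusted over the list alone, with a median of 9.41 that was the same with 1 member at its bound (adjusted p = 0.0157, and adjusted p = 0.59 with an estimated correlation), and Apoa1 and Trf rose by 10.76 ± 2.01 and 5.17 ± 1.36. Mesothelium genes rose in 3 of 5 cases, or 4 adjusted over the list alone (adjusted p = 0.0187, and adjusted p = 0.338 with an estimated correlation), with Msln higher by 4.25 ± 1.11, or 3.15 ± 1.02 without orthotopic replicate 2 (adjusted p = 0.0975). Immediate early genes rose in 6 of 18 cases, also 6 adjusted over the list alone (adjusted p = 0.00915, and adjusted p = 0.265 with an estimated correlation). TGF-beta target genes rose in 4 of 18, also 4 adjusted over the list alone (adjusted p = 0.029, and adjusted p = 0.472 with an estimated correlation). Within these lists Fos, Junb and Id1 were higher by 1.88 ± 0.24, 1.22 ± 0.15 and 2.31 ± 0.39. Without orthotopic replicate 3 the smooth muscle, pancreas and liver, mesothelium and immediate early lists had 10, 4, 2 and 6 members higher, and the pancreas and liver median was 1.81, against 10.58 without orthotopic replicate 1 and 10.27 without subcutaneous replicate 3. Apoa1 and Trf had log2 fold changes of 7.71 ± 0.77 and 2.52 ± 0.47 without orthotopic replicate 3, and Apoa1 11.38 ± 2.70 without subcutaneous replicate 2 (adjusted p = 0.0559). The fibroblast, endothelium and TGF-beta target lists did not pass without orthotopic replicate 3 (adjusted p = 0.515, 0.213 and 0.247), nor the fibroblast list without subcutaneous replicate 3 (adjusted p = 0.172). Lists that did not pass included T cell genes with 0 of 5 higher, cytotoxic and NK cell genes with 2 of 6, dendritic cell genes with 2 higher and 1 lower of 13, mast cell genes with 2 of 11 and cholesterol synthesis genes with 4 of 20, the same adjusted over the list alone. For the p53 target list, also not past the threshold, the median and mean (0.05 and 0.06) and the test differed in sign.

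Among driver genes in the site comparison, Myc had a log2 fold change of -2.91 ± 0.34 (adjusted p = 0.00872), Ccne1 -1.71 ± 0.25, Cdk6 -0.91 ± 0.23 and Arid1a -0.48 ± 0.12, while Egfr rose by 1.13 ± 0.22 and Tgfbr2 by 1.19 ± 0.23. Adjusted over the list alone, 4 of 30 members were higher and 7 lower. Trp53 (-0.71 ± 0.23), Smad4 (-0.50 ± 0.15), Cdh1 (1.60 ± 0.50), Cdkn2a (-1.23 ± 0.51) and Apc (-0.45 ± 0.19) did not pass. The groups did not overlap for 48.5% of genes, where chance gives 10%. In the authors' deposited table for the sites, 6343 of 16858 genes had an adjusted p under 0.05. Leaving out orthotopic replicate 1 or 2 reduced the genes past the threshold to 1221 and 387, and leaving out subcutaneous replicate 2 or 3 to 1648 and 2094. Of 55 calls on named genes 24 passed in every planned setting, namely Gkn1, Gkn2, Cldn18, Reg3b, Gjb1, Vil1, Slitrk5, Tff2, Pgc, Muc6, Cdc20, Kif11, Cdk4, Irf7, Irf9, Tap1, Psmb9, Il33, Dcn, Abcc9, Mylk, Fos, Junb and Myc. Leaving out orthotopic replicate 1, 2 or 3 or subcutaneous replicate 1, 2 or 3 ended 16, 30, 4, 6, 21 and 17 of those calls, with the highest adjusted p at 0.101 (Cdk6), 0.109 (Krt8), 0.0599 (Kdr), 0.0865 (Trf), 0.115 (Kdr and Trf) and 0.104 (Kdr).

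**Figure D3:**
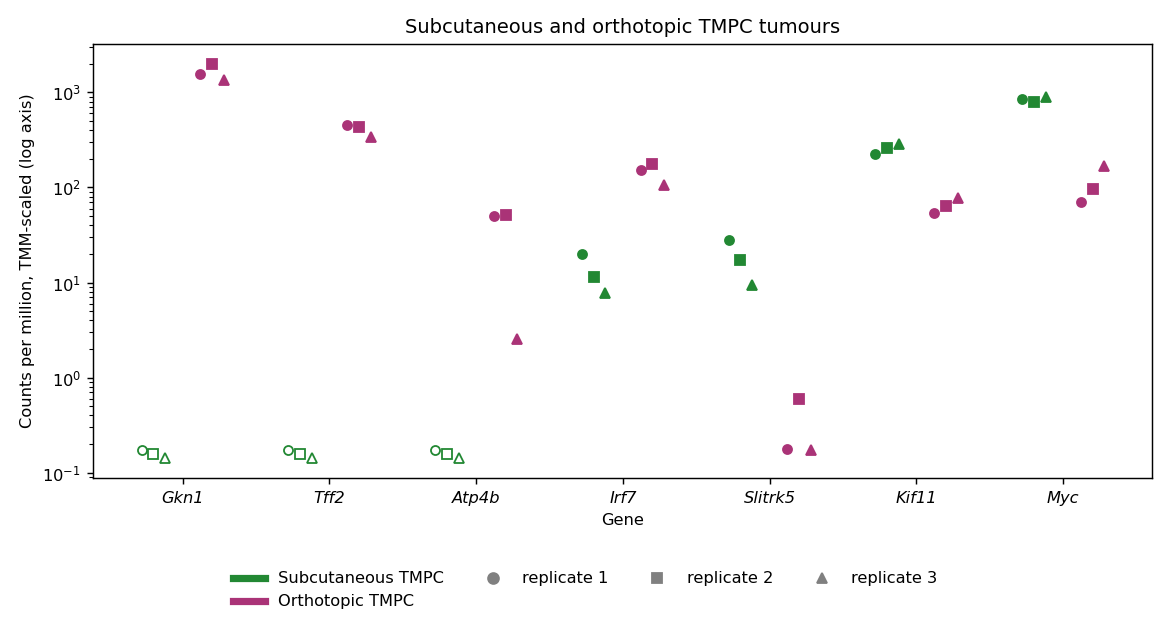
CPM scaled by TMM (vertical log axis) of 7 genes (horizontal axis) in the 3 subcutaneous and 3 orthotopic TMPC libraries, with a point per library and open points for values of under 3 counts, drawn at the level of 3 counts. Slitrk5 lies at 9.47 to 28.1 in subcutaneous and at most at 0.601 in orthotopic tumours, and Atp4b at 50.6, 51.4 and 2.55 in the orthotopic libraries.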

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

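Tests on other splits of the libraries were chosen only after the results were seen, as were the settings that joined 2 changes, the lists fitted on only the TMP and TMPC groups, and the shared calls without TM replicate 2. In edgeR, other size factors, no filter on low counts and a filter at a mean count of 100 gave 3816 to 4234 genes for TMP against TM, 4804 to 5464 for TMPC against TM and 3797 to 4153 for the sites. TMPC against TMP had 0 genes in every edgeR setting, with 190 to 1345 genes at an unadjusted p under 0.05, and 16 genes in DESeq2. DESeq2 called 5734, 6819 and 6371 genes in the comparisons of TMP with TM, of TMPC with TM and of the sites. Of its calls on simulated data 33.5% to 38.2% fell on unchanged genes, or 54 to 68 genes per comparison. Few genes were changed in those data, so that share does not carry over to the far more numerous real calls. A fold threshold of 1 on the log2 scale left 2773, 3824 and 2718 genes, fewer by construction. Fitting only the 2 groups compared gave 3248 and 3536 genes for TMP and TMPC against TM, where fewer libraries estimate the spread. With an estimated correlation, camera passed 0 lists in each of the 4 comparisons, with 2, 4, 2 and 6 lists at an unadjusted p under 0.05, against 16, 16, 18 and 25 past the threshold at the preset correlation. It also passed 0 lists when TM replicate 2 or orthotopic replicate 3 was left out as well, with 3, 3 and 9 at an unadjusted p under 0.05. On only the TMP and TMPC groups 14 lists passed, and without TMPC replicate 1 there 17 lists and 0 genes. Shared calls of the comparisons with TM numbered 5132 in DESeq2, 3571 without a filter and 4517 without TM replicate 2. The replicate numbers were not taken to pair the libraries, since in no comparison did all 3 same-numbered pairs correlate at over 0.1. For TMP against TM these correlations ran from 0.0854 to 0.284, with 2 of 3 over 0.1, and 5 of 6 libraries correlated best with their own number, a hint from the data and not from the design. Elsewhere they ran from -0.237 to 0.287, and 2 of 6 libraries in TMPC against TMP, 3 of 6 in TMPC against TM and 2 of 6 for the sites correlated best with their own number. With the number as a block, genes numbered 3032, 0, 4295 and 1777 and lists 18, 14, 19 and 27 in the comparisons of TMP with TM, TMPC with TMP, TMPC with TM and the sites. Among genes chosen after their values were seen, Hspa1a and Hspa1b for TMP against TM (adjusted p = 0.0893 and 0.0528), Dram1 for TMPC against TM (adjusted p = 0.0543) and Notum, Lef1, Herpud1, Dnajc3 and Dnajb9 for the sites (adjusted p = 0.0533, 0.11, 0.0527, 0.0588 and 0.0809) did not pass with the block.

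Leaving out 1 library gave 1550 (without TMP replicate 1) to 4885 genes (without TM replicate 2) for TMP against TM. For TMPC against TM it gave 3414 (without TMPC replicate 2) to 6390 (without TM replicate 2). The sites had 387 (without orthotopic replicate 2) to 4789 genes (without orthotopic replicate 3). Lists numbered 15 to 19, 17 to 20 and 17 to 28 in these comparisons, and 9 (without TMPC replicate 3) to 17 (without TMP replicate 1 or TMPC replicate 1) for TMPC against TMP. An arm left with 2 libraries shared the spread of the others in the fit. None of the genes past the threshold in the reported comparisons changed sign in any of these settings of the gene test (0 genes). Of 1851 values of the 161 results on named genes under the other settings, 1615 kept their direction and side of the threshold, 212 no longer passed, 12 newly passed and 12 reversed. Another 21 had no value, 16 of them in DESeq2. Of 243 such values of 21 genes chosen after their values were seen, 185 kept both, 56 no longer passed, 1 newly passed and 1 reversed. None of the reversed results had passed in its comparison, and the lowest adjusted p among the reversed values was 0.473. Under the block, Cdh1 had a log2 fold change of 0.11 for TMP against TM and Cdkn2a of -0.12 for TMPC against TMP, and at a mean count of 100 Smad4 had -0.0212 for TMPC against TM. When libraries were left out in turn, values for TMP against TM ran from -0.68 to 0.30 for Cdh1, from -0.31 to 0.12 for Smad4 and from -0.0374 to 0.26 for Arid1a. For TMPC against TMP they ran from -0.19 to 0.71 for Myc and from -0.47 to 0.30 for Cdkn2a. For TMPC against TM they ran from -0.14 to 0.31 for Smad4 and from -0.0334 to 0.51 for Mdm2, which was chosen after its values were seen. Except where stated, the cause was not tested. Alternatives with a pseudocount were not run, since the values are counts. Depth limits levels under 0.142 to 0.181 CPM, the size of 3 counts.

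For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real splits gave 4239, 5469 and 4204 genes for TMP against TM, TMPC against TM and the sites, where the highest of the other splits gave 0, so that 1 split in each was as large. For TMPC against TMP, 10 splits gave as many genes as the real one, which gave 0, as did the highest of the others. As many lists as in the real split were reached by 10 splits for TMP against TM (16, highest other 24), 2 for TMPC against TMP (16, highest other 18), 8 for TMPC against TM (18, highest other 24) and 3 for the sites (25, highest other 26). Of 60 splits of the 9 subcutaneous libraries into a control and 2 other groups, the real one and 59 drawn at random from 840, 2 gave as many shared calls, the real one with 3926 and another with 3996, both with the 3 TM libraries as the control group and the second with TMP and TMPC libraries mixed. The other 58 gave 0. Of the splits drawn, the share as large was under 0.05, in a test chosen after the results were seen. The splits speak only to the TM libraries standing apart from the rest, which was already seen when the test was chosen, so they do not exclude chance. They also do not show whether TMP and TMPC tumours share calls beyond that.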

Other observations

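The tests on TM replicate 2, on Xist and on gastric genes were chosen only after the results were seen, and so were the genes named here, while the list tests were planned. In TMPC against TM tumours, p53 target genes rose in 3 of 25 cases and fell in 2, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.819, and adjusted p = 0.959 with an estimated correlation). Ddit4, an inhibitor of mTOR signalling, rose by 3.95 ± 0.39 (log2, SE), Tigar, which limits glycolysis, by 1.09 ± 0.19 and the pro-apoptotic gene Bax by 0.71 ± 0.16. The autophagy gene Dram1 and the death receptor gene Fas had log2 fold changes of -2.48 ± 0.63 and -2.24 ± 0.63, which were -1.28 ± 0.26 and -1.07 ± 0.31 without TM replicate 2. Neither passed without TMPC replicate 2 (adjusted p = 0.0662 and 0.0604) or 3 (adjusted p = 0.0581 and 0.0772), nor did Fas without TMPC replicate 1 (adjusted p = 0.0727) or with only the 2 groups compared (adjusted p = 0.0664), in ranges of 0.00039 to 0.0662 and 0.00159 to 0.0772 over the alternatives. Cdkn1a and Mdm2, further targets of p53, did not pass at 0.45 ± 0.57 and 0.09 ± 0.26 (adjusted p = 0.559 and 0.796). Without TM replicate 2 Mdm2 rose by 0.51 ± 0.13 (adjusted p = 0.016, in a range of 0.016 to 0.978), Cdkn1a had 1.24 ± 0.48 (adjusted p = 0.0737), and 4 members of the list rose and 2 fell. In TMP against TM tumours, immediate early and stress genes rose in 4 of 18 cases and fell in 2, or 4 and 4 adjusted over the list alone (adjusted p = 0.86, and adjusted p = 0.888 with an estimated correlation), and the counts were 3 and 3 without TM replicate 2. The chaperone genes Hsph1, Dnajb1, Hspa1b and Hspa1a rose by 2.26 ± 0.52, 0.78 ± 0.18, 1.46 ± 0.36 and 1.19 ± 0.38, the last pair uncertain because their sequences are nearly identical. The transcription factor gene Fos fell by 1.81 ± 0.30 and Zfp36, which promotes mRNA decay, fell by 2.13 ± 0.46, or by a log2 fold change of -1.34 ± 0.20 without TM replicate 2. Calls were lost without TMP replicate 1 for Zfp36, Dnajb1, Hspa1b and Hspa1a (adjusted p = 0.0595, 0.0546, 0.0735 and 0.153) and without TMP replicate 2 for Hsph1, Hspa1b and Hspa1a (adjusted p = 0.0526, 0.0653 and 0.0954). They were lost without TMP replicate 3 for Dnajb1, Hsph1, Hspa1b and Hspa1a (adjusted p = 0.0624, 0.0515, 0.0572 and 0.0966), without TM replicate 1 for Hspa1b and Hspa1a (adjusted p = 0.0549 and 0.101) and without TM replicate 2 for Hspa1a (adjusted p = 0.0539). Hspa1a also did not pass with other size factors, no filter on low counts, a filter at a mean count of 100 or only the 2 groups compared (adjusted p = 0.0519, 0.0513, 0.0552 and 0.0675), and passed in 2 of 12 alternatives.

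In orthotopic against subcutaneous TMPC tumours, unfolded protein response genes rose in 4 of 20 cases and fell in 1, the same adjusted over the list alone (adjusted p = 0.651, and adjusted p = 0.843 with an estimated correlation), and the counts were 3 and 1 without orthotopic replicate 3. Besides Xbp1, the chaperone cofactor genes Dnajc3 and Dnajb9 rose by 1.02 ± 0.21 and 0.72 ± 0.17 and Herpud1, a gene of protein degradation at the endoplasmic reticulum, by 0.89 ± 0.18. Asns, which encodes asparagine synthetase, had a log2 fold change of -1.08 ± 0.15. Stem cell and Wnt target genes rose in 2 of 16 cases and fell in 2, the same adjusted over the list alone (adjusted p = 0.707, and adjusted p = 0.84 with an estimated correlation), with 3 and 1 when orthotopic replicate 3 was left out. Olfm4, a marker of intestinal stem cells, rose by 5.55 ± 0.76 and the Wnt inhibitor gene Notum by 2.61 ± 0.58. Bmi1, a Polycomb gene, had a log2 fold change of -0.86 ± 0.17 and the Wnt transcription factor gene Lef1 of -3.32 ± 0.96. Olfm4 passed in every planned setting, with 4.68 ± 0.56 without orthotopic replicate 1. Notum did not pass without orthotopic replicate 1 or 2 or subcutaneous replicate 2 or 3 (adjusted p = 0.0675, 0.0824, 0.089 and 0.0674). Bmi1 did not without orthotopic replicate 1 or 2 (adjusted p = 0.0617 and 0.0597), nor Asns without orthotopic replicate 2 (adjusted p = 0.0513). Herpud1 and Dnajc3 did not pass without orthotopic replicate 1 (adjusted p = 0.0623 and 0.0522), orthotopic replicate 2 (adjusted p = 0.0639 and 0.0665) or subcutaneous replicate 2 (adjusted p = 0.0797 and 0.0713). The call of Dnajb9 was lost without each of the 6 libraries in turn, at adjusted p values from 0.0521 without orthotopic replicate 3 to 0.0832 without orthotopic replicate 1. That of Lef1 was lost without each of 5 libraries in turn, at adjusted p values of 0.0931 and 0.112 without subcutaneous replicates 1 and 2 and of 0.135, 0.087 and 0.0879 without orthotopic replicates 1, 2 and 3.

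Against the mean of TM replicates 1 and 3, columnar epithelial genes in TM replicate 2 lay at a median log2 ratio of -4.19 (quartiles -4.41 and -3.43), B cell and plasma cell genes at 5.46 and adipocyte genes at 10.8, with the fat cell gene Adipoq at 375 CPM against 0 and 0.227 and the lipid synthesis gene Scd1 at 15400 CPM against 38.7 and 50.9. Lower depth is argued against by its total count, 95.6% of the lowest of the other 11 libraries, and by the lists that stood above the others. Host tissue with few tumour cells in the piece taken is a candidate explanation, since low epithelial and high host cell genes were both present, although fibroblast genes lay at -1.88 and 5 of 8 B cell and 6 of 13 adipocyte genes also reached a mean of 1 CPM in TM replicates 1 and 3. A wrong label or a tumour of other cells cannot be told apart from host tissue with next to no tumour cells. Either would give 0 reads of the 4 Y-linked genes, against 2179 and 2303 in TM replicates 1 and 3. The same holds for 0 reads of Sox2, against 180 and 242 CPM there. Tumour cells like those of replicates 1 and 3, at a share matching the columnar median of -4.19, would have left reads of these genes. No biological explanation was tested, as the labels give no difference between libraries of a group.

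Xist stood at 324, 1250 and 200 CPM per total count in the 3 TM libraries and at most at 12.4 in the other 9, while TM replicates 1 and 3 also held Y-linked reads, at 123 and 110 CPM. Fewer cells of a female host in TMP and TMPC tumours are argued against as the whole cause, since 44 fibroblast and endothelium genes had a median log2 fold change of -0.25 (quartiles -0.78 and 0.12) without TM replicate 2, where Xist had -7.80 ± 1.58 for TMP against TM. The corresponding values for TMPC against TM were -0.53 (quartiles -1.30 and -0.11) and -5.72 ± 1.40. Hosts of another sex in the TM group are a candidate explanation that cannot be told apart from other differences that go with the group, because the labels give no sex of the hosts. The same limit holds for all genes, lists and shared calls of the comparisons with TM.

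Gastric genes in the orthotopic tumours came with 11 of 16 smooth muscle and pericyte genes higher and with the stomach regional factor genes Barx1 and Pdx1 at 19.4 to 28.7 and 2.93 to 4.44 CPM, against at most 0.0534 and 0 CPM in subcutaneous tumours. Stomach wall of the host in the pieces taken is a candidate explanation, in line with the smooth muscle genes, although 15 of 15 such genes tested with the subcutaneous libraries reached a mean of 1 CPM in subcutaneous TMPC tumours. Counts of the parietal gene Atp4b per count of the pit gene Gkn1 were 0.0325, 0.0257 and 0.00188 in the 3 orthotopic libraries, a 17.3-fold range. Dilution of tumour cells as the reason for the lower Myc (-2.91 ± 0.34) cannot be told apart from a change in the tumour cells, because the 33 genes tested (median 0.102, quartiles -0.991 and 0.742, with 3 within 1 of Myc or lower) were chosen for at most 3 counts in TM replicate 2, not for absence from stomach. Expression of gastric genes by the tumour cells at this site was not tested and stays open.

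In orthotopic replicate 3 the pancreas genes Amy2a5 and Ctrb1 stood at 588 and 163 CPM, against at most 2.49 and 0.924 CPM in the other orthotopic libraries, and the hormone gene Ghrl at 6.33 CPM against 277 and 213.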
